A study of Homo sapiens with 9 samples.

How the data were processed

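RNA from primary human erythroid progenitor cells was measured on 9 Affymetrix human expression arrays. Per the labels' protocols, CD34-positive cells came from bone marrow or cord blood, and which source belongs to which array is not given. The cells were driven into the erythroid lineage in a culture of 2 steps, of which the first lasted 7 days, and RNA was linearly amplified before labelling. The series holds 2 untreated arrays at 6 hours, 5 untreated arrays at 3 days and 2 arrays of cells kept for 3 days in 2 µM NK57, a compound known here only by its code name. The labels number the 3-day untreated arrays 1a, 3a, 1b, 2b and 3b and do not explain the letters. A difference in cell source between the NK57 and untreated arrays cannot be told apart from the treatment. Nothing in the labels says that arrays came from separate cultures or donors, so p-values measure only the spread between these arrays, which may be technical (the counts with the NK57 arrays averaged to 1 sample are 469 higher and 73 lower).

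The deposited values are linear intensities, one per probe set and array, and RMA is named in the submitters' processing notes, with software and version not given in the sources used here. RMA corrects the background, brings arrays to a common distribution and summarises probes, so a change shared by most genes is partly removed. The median deposited intensity was 39.2 and 39.1 on the NK57 arrays and lay between 40.9 and 42.4 on the untreated arrays. The mean was 166.1 and 166.8 on the NK57 arrays, against 151.5 to 159.4 on the untreated arrays. The deposited distributions thus still differed along with treatment. The alternative scalings given below show how far the counts depend on this. The values were log2 transformed with no offset.

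Of 22283 probe sets, 68 were controls, 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 had none. Symbols were updated through the gene identifier for 19059 probe sets, and 79 probe sets that report a donor's sex or a common genotype were left out throughout. A gene was represented by its probe set with the highest mean over all arrays, which gave 11910 genes. Genes above the 25th percentile of all values on at least 2 arrays were tested, in number 9364. HBG1 and HBG2, and likewise HBA1 and HBA2, share their probe sets and were measured only as pairs.

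One limma model (version 3.58.1, R 4.3.3; lmFit and eBayes) with 3 groups was fitted to all 9 arrays, with 6 residual and 6.12 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Errors of changes are standard errors of that fit and intervals are 95% intervals. The arrays' number limits the precision. Gene lists, 20 of pathways and 8 of cell type markers, were fixed before the data were examined, with erythroid maturation, fetal globin and histone deacetylation among their subjects. The fetal globin and deacetylase lists were chosen from recollection of the study, since the labels name neither subject nor a target of NK57. They held 440 genes, of which 322 were tested. Lists were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Genes were named by a rule fixed at the same time. It took the 8 largest rises and falls among called genes with no overlap between groups, up to 2 called members per list, and a fixed set of globin and regulator genes. With no called gene, the 5 smallest p in each direction were given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

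The model was tested on simulated data with 9364 genes, 200 of them changed. For the NK57 comparison it recovered 32.8% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2, and 1.91% of its calls were false. For the time comparison it recovered 28.4%, 95.5% and 100%, and 7.45% of its calls were false. With no change simulated there were 0 calls in either comparison. The simulated values were independent draws, with no difference between letters, no batch and no correlation between genes. These rates therefore need not hold for the real arrays.

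Alternatives fixed beforehand covered scaling, filtering, probe set choice, an offset of 16 before the log, array weights, the controls used, the replicate number as a block and leaving out each array. A list or gene count was held to be the same within 1.5 times. A named gene was held to be reversed only if its sign changed and it was called in either fit.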

Results

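Gene expression was profiled in primary human erythroid progenitor cells, the precursors of red blood cells, that were left untreated or exposed to NK57. The labels do not say what NK57 acts on. There were 2 untreated arrays at 6 hours, 5 untreated arrays at 3 days and 2 arrays after 3 days in 2 µM NK57. Values are log2 intensities, given as mean ± SD over arrays, and changes are log2 differences with their standard error (SE).

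The arrays differed in ways that treatment and time did not describe. The NK57 arrays were the closest of all pairs, with an SD of 0.13 in the log2 difference across genes. The next closest pair was untreated 6-hour replicate 2 and untreated 3-day replicate 1a, at 0.19, whereas the 6-hour arrays differed from each other by 0.31. Among the untreated 3-day arrays, those with the letter b had higher tryptase genes, TPSAB1 by 2.62 and TPSB2 by 2.73, higher IFITM3 by 2.21, and lower FOS and HBD, with changes of -2.55 and -1.33. In a limma model with the letters as groups, 260 genes were higher and 214 lower in letter b (n = 3) than in letter a (n = 2). The 18S ribosomal RNA control signal was 6.93 ± 0.69 in letter b, 8.19 ± 0.87 in letter a, 9.40 ± 0.45 at 6 hours and 10.35 ± 0.17 under NK57. The first principal component held 49.8% of the variance and set the NK57 arrays apart, and the second held 20.1% and set letter b apart from letter a.

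The first comparison asked what 3 days of NK57 changed against untreated cells of the same age. HPGD, the enzyme that degrades prostaglandins, showed the largest rise, from 5.66 ± 0.42 (n = 5) to 9.85 ± 0.07 (n = 2), an 18.3-fold difference (adjusted p = 2.6e-06). HPGDS, the hematopoietic prostaglandin D synthase, rose by 2.74 ± 0.18 (SE). ANXA1 rose by 2.34, the glycolytic enzyme ENO1 by 2.30, the mitochondrial folate carrier SLC25A32 by 2.27, TMEM123 by 2.19, the IgE receptor chain FCER1A by 2.13 and SAMSN1 by 2.13. In untreated 3-day cells SLC25A32, FCER1A and SAMSN1 were low, at 4.62, 4.73 and 5.02, where the filter's 25th percentile was 4.63. The sizes of these rises may therefore depend on the background. The largest falls were those of IFITM3 (-2.09 ± 0.60), the cystine transporter SLC7A11 (-1.98 ± 0.18), GDF15 (-1.97), the serine synthesis enzyme PSAT1 (-1.95), DDIT4 (-1.89), ATF5 (-1.84), ARG2 (-1.80) and TRIB3 (-1.75). The IFITM3 change was -0.76 against letter a and -2.97 against letter b. Falls of GDF15, ARG2 and TRIB3 did not pass against letter a alone, at adjusted p = 0.0631, 0.0720 and 0.0593. Their changes there, -2.01, -2.35 and -2.05, were no smaller than against all 5 untreated 3-day arrays. ARG2 did not pass against letter b either, at adjusted p = 0.0867, with a change of -1.44.

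**Figure D1:**
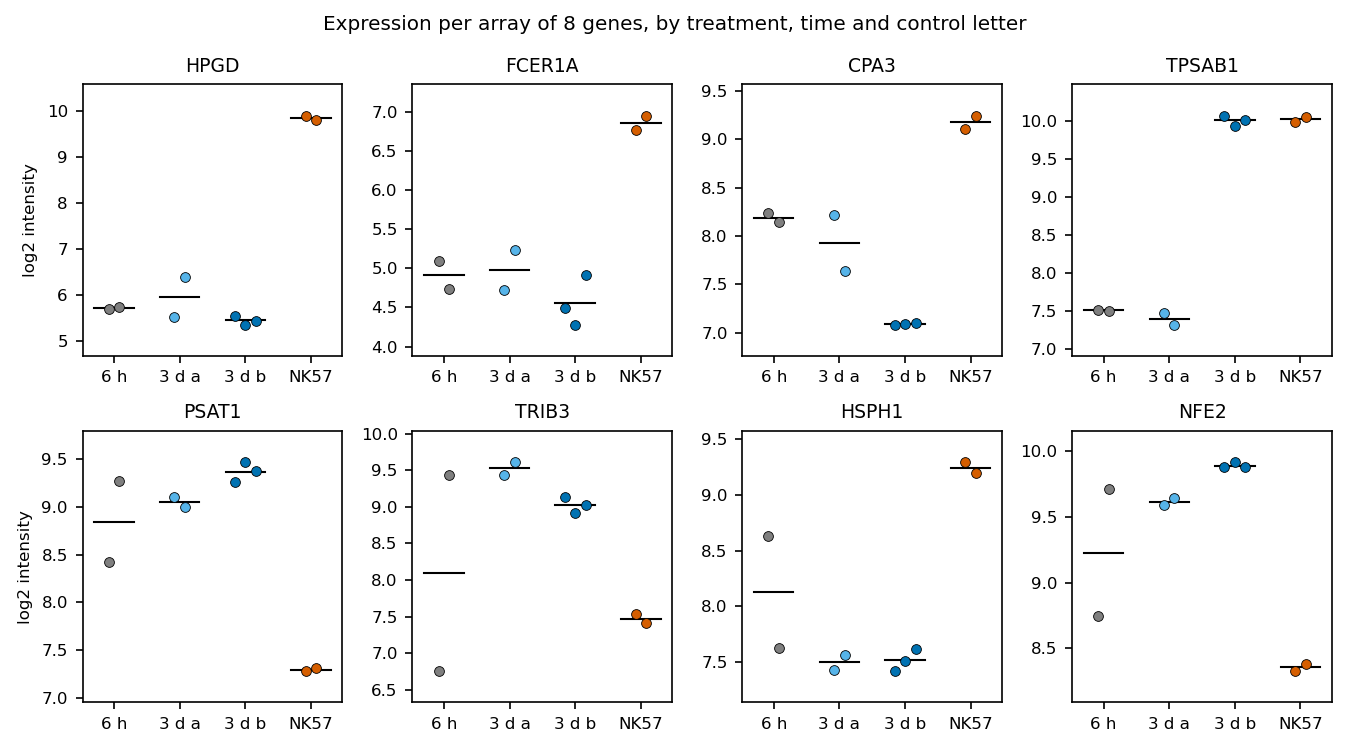
Log2 intensity of 8 genes on each array (points), with the mean of each set of arrays as a line, for untreated cells at 6 hours, untreated 3-day cells of letters a and b, and NK57-treated cells. Vertical axes differ between genes. HPGD was near 5.66 in untreated 3-day cells and 9.85 under NK57, while TPSAB1 in NK57-treated cells matched letter b and not letter a.

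Genes of the unfolded protein and amino acid stress list fell together. Of 14 tested members 10 fell and 1 rose, with a median change of -1.12 (camera adjusted p = 6.4e-05, and adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. PSAT1, DDIT4, PHGDH, CEBPB and ASNS, which respond to amino acid shortage, were among those that fell, and the member that rose was HSPA5, a chaperone of the endoplasmic reticulum. Against letter a alone 10 members fell, and against letter b alone 10. The list score, the mean of the members centred over the 9 arrays, was -0.67 and -0.73 on the NK57 arrays, between 0.23 and 0.38 on the untreated 3-day arrays, -0.42 on 6-hour replicate 1 and 0.30 on 6-hour replicate 2.

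Heat shock genes and genes of ribosome biogenesis rose. Of 9 heat shock genes 6 rose, with a median of 0.85 (camera adjusted p = 2.3e-04, and adjusted p = 0.399 with an estimated correlation). HSPH1 rose by 1.74 ± 0.20 and HSPA4 by 1.48 ± 0.19. Adjusted over the list alone, 7 of the 9 rose. Of 14 MYC and ribosome biogenesis genes 8 rose and 0 fell, with a median of 0.62 (camera adjusted p = 3.8e-05, and adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 11 rose. The ribosome assembly factors WDR12 and NOP16 rose by 1.02 ± 0.12 and 1.57 ± 0.24, and MYC itself had a change of 0.63 that did not pass. MYC passed against letter a alone, at 1.13 (adjusted p = 0.0145), and not against letter b alone, at 0.29 (adjusted p = 0.0703). On 6-hour replicate 1 the heat shock score was 0.34, against -0.31 on 6-hour replicate 2 and 0.58 and 0.60 on the NK57 arrays. The ribosome biogenesis score was 0.12 and -0.24 on 6-hour replicates 1 and 2, and 0.49 on both NK57 arrays.

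Of 5 red cell lists 3 were called as lower, those of heme synthesis, of the red cell membrane and of erythroid transcription factors, and the iron and globin lists were not (camera adjusted p = 0.35 and 0.722). Heme synthesis genes fell in 6 of 8 cases, with a median of -0.75 (camera adjusted p = 0.0034, and adjusted p = 0.399 with an estimated correlation), among them PPOX (-1.17 ± 0.15), UROD (-0.77 ± 0.10) and ALAS2 (-0.83 ± 0.23), the first enzyme of the pathway in red cells. Of 15 red cell membrane and surface genes 10 fell, with a median of -0.79 (camera adjusted p = 8.1e-04, and adjusted p = 0.399 with an estimated correlation), led by the water channel AQP1 (-1.44 ± 0.24) and the glucose transporter SLC2A1 (-1.04 ± 0.17). Of 12 erythroid transcription factors 6 fell, with a median of -0.49 (camera adjusted p = 0.0094, and adjusted p = 0.413 with an estimated correlation). That call was lost in the fit with letter a controls alone (adjusted p = 0.0656), though not against letter a in the model with the letters as groups (adjusted p = 0.0338), and it was lost with the 18S signal as a covariate (adjusted p = 0.0573). NFE2 fell by 1.43 and FOXO3 by 1.28. KLF1 and GATA1, with changes of -0.70 and -0.48, passed against the 5 untreated 3-day arrays (adjusted p = 0.0294 and 0.04996) but not against letter a alone (adjusted p = 0.204 and 0.288), nor without replicate 1b, 2b or 3b. GATA1 lost its call in 19 of 27 other settings, among them all 7 untreated arrays as controls. ALAS2 did not pass against letter a alone (adjusted p = 0.0577), though its change there was -0.97, and -0.73 against letter b. Against letter a alone 4 heme synthesis genes, 6 membrane genes and 3 transcription factors fell. Against letter b alone 6, 11 and 10 fell, and 1 transcription factor rose. Adjusted over the list alone, 7 heme synthesis genes, 11 membrane genes and 8 transcription factors fell, and 1 membrane gene and 1 transcription factor rose. Of the iron genes, ACO1 rose by 0.76 ± 0.11 and TFR2 fell by 0.72 on the log2 scale, and 5 of 9 did not pass. On 6-hour replicate 1 the scores of the heme, membrane and transcription factor lists were -0.14, -0.06 and -0.23, against 0.23, 0.24 and 0.19 on 6-hour replicate 2 and between -0.41 and -0.48 on the NK57 arrays.

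**Figure D2:**
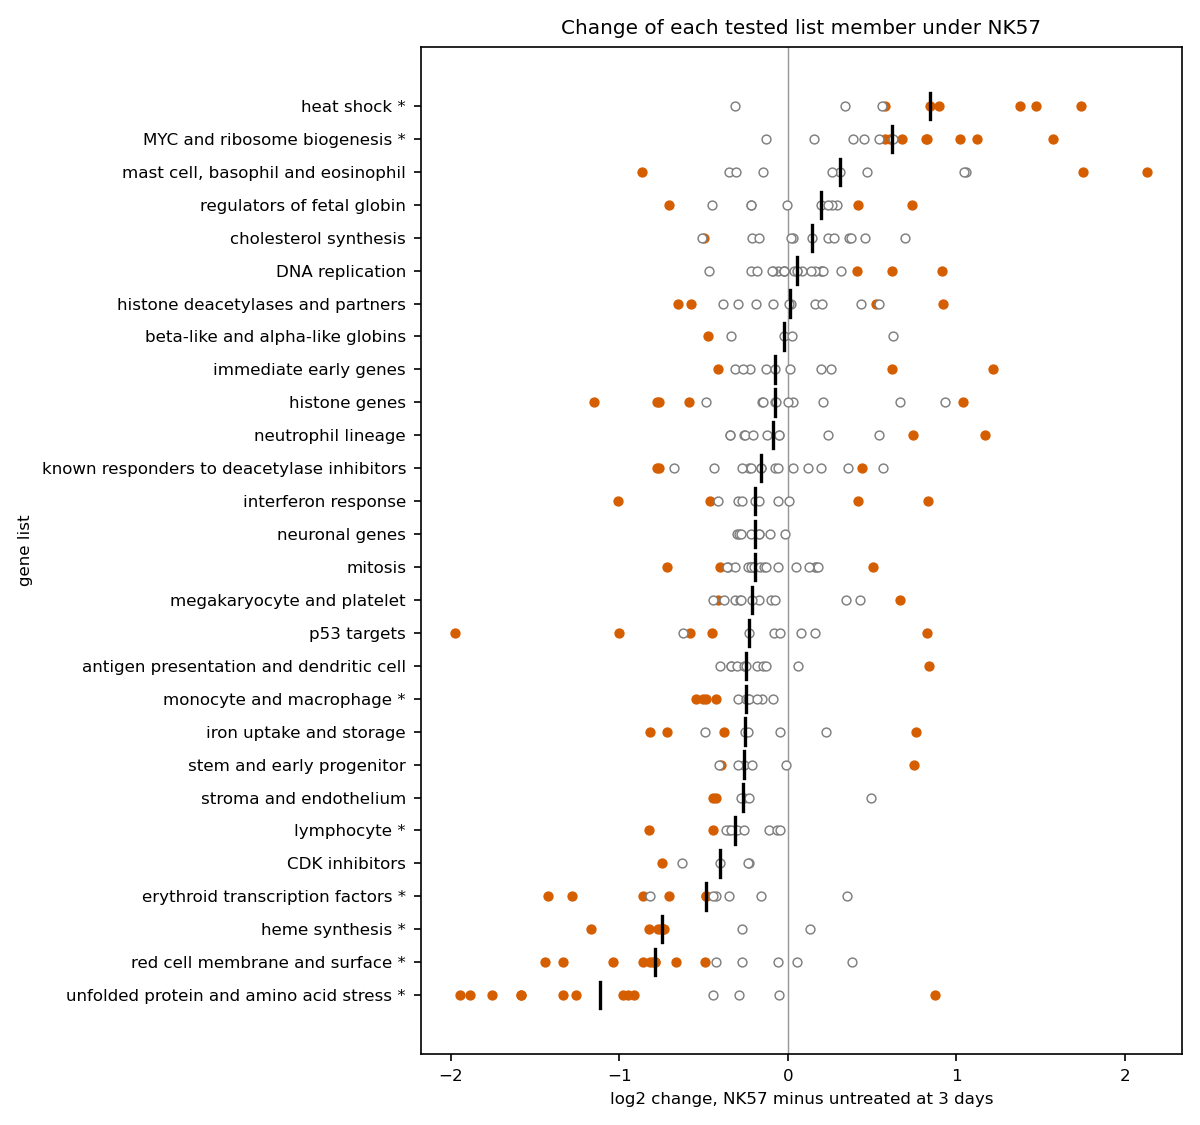
Log2 change under NK57 of each tested member (points) of the 28 gene lists, with list medians as bars. Filled points are genes with adjusted p under 0.05. An asterisk marks the 8 lists called by camera with the preset correlation. Of these, 0 were called with an estimated correlation, and 8 had a fry adjusted p under 0.05 (0.0038 to 0.0193). Fry also gave 0.0064 for CDK inhibitors, 0.0073 for the mast cell, basophil and eosinophil list and 0.0198 for neuronal genes, which camera did not call. Medians ran from -1.12 for the amino acid stress list to 0.85 for heat shock.

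Markers of other blood cell types moved in several directions. In the mast cell, basophil and eosinophil list FCER1A and CPA3, the mast cell carboxypeptidase, rose by 2.13 ± 0.22 and 1.75 ± 0.26, and EPX, the eosinophil peroxidase, fell with a change of -0.86, though not against letter a alone (-0.60, adjusted p = 0.126), while 8 of the 11 tested genes did not pass and the list was not called (camera adjusted p = 0.316). The list's call depended on the controls. In the model with the letters as groups it was called as higher against letter a (camera adjusted p = 0.0231) and against the 6-hour arrays (0.0021), and not against letter b (0.316). The tryptase genes depended on them as well. TPSAB1 was 2.63 ± 0.13 above letter a (adjusted p = 4.0e-08) and 0.01 ± 0.12 above letter b (95% interval -0.24 to 0.27, adjusted p = 0.930). CPA3 was above both, by 1.25 ± 0.17 and 2.09 ± 0.15. The monocyte list fell (4 of 11 genes, median -0.25, camera adjusted p = 0.0348, and adjusted p = 0.399 with an estimated correlation), as did the lymphocyte list (2 of 11 genes, median -0.31, camera adjusted p = 0.0358, and adjusted p = 0.413 with an estimated correlation). Neither call held under quantile normalization, and in the model with the letters as groups the monocyte list had adjusted p = 0.0565 against letter a and 0.0535 against letter b, and the lymphocyte list 0.0278 and 0.0951. All 11 tested genes of either list had changes below 0, but so had all 8 neuronal genes (median -0.19) and 5 of 6 stroma and endothelium genes. The median over all genes tested was -0.09, so a downward shift not particular to these cell types stays open. Among neutrophil lineage genes MS4A3 rose by 1.17 ± 0.23 and MPO by 0.74 ± 0.23, and the list was not called (adjusted p = 0.953). Against letter a alone MS4A3 rose by 0.70 and MPO did not pass, at 0.31 (adjusted p = 0.145), and MPO also did not pass under quantile normalization or without replicate 1b, 2b or 3b.

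Globin genes and their regulators were listed from recollection of what the study was about, which the labels do not state. Fetal globin (HBG1 and HBG2) is replaced by adult globin (HBB and HBD) after birth. The mean of the 3 probe sets shared by HBG1 and HBG2 was 13.07 ± 0.30 in untreated 3-day cells and 13.07 ± 0.004 under NK57. Against letter a, at 12.75 ± 0.07, the difference was 0.32 ± 0.14 (95% interval 0.01 to 0.63, adjusted p = 0.109). Against letter b, at 13.28 ± 0.09, it was -0.21 ± 0.13 (95% interval -0.49 to 0.07, adjusted p = 0.223), so neither difference passed. HBB was 14.12 ± 0.02 and 14.10 ± 0.02, close to the top of the arrays' range, where changes are compressed. The mean of the probe sets shared by HBA1 and HBA2 was 13.71 ± 0.09 and 13.64 ± 0.01. These and the fetal globin probe sets lay not far below that top, so their changes may be compressed too. HBZ was low, at 5.80 ± 0.34 and 5.83 ± 0.11. HBD differed by 0.62 ± 0.40 (adjusted p = 0.237), with -0.17 against letter a (adjusted p = 0.506) and 1.15 against letter b, where it passed (adjusted p = 0.00103). HBE1 fell by 0.47 on the log2 scale (adjusted p = 0.0302), from a low level of 6.83, and its other probe set showed a change of -0.03 ± 0.15. HBE1 had a change of -0.49 against letter a alone that did not pass (adjusted p = 0.0971), and of -0.46 against letter b. It also did not pass with arrays centred on their medians or with the mean of its probe sets. Of 11 regulators of fetal globin 2 rose and 1 fell, and the list was not called (camera adjusted p = 0.676). MBD2 rose by 0.74 ± 0.19, HBS1L, named after its value was seen, by 0.42, and KLF1 fell. MBD2 and HBS1L did not pass against letter a alone, at 0.46 and 0.38 (adjusted p = 0.0946 and 0.137). Against letter b they were at 0.93 and 0.44. With the mean of its probe sets the change of MBD2 was -0.013. BCL11A had a change of -0.45 (95% interval -0.93 to 0.04, adjusted p = 0.140) and MYB one of -0.01 (95% interval -0.38 to 0.37).

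**Figure D3:**
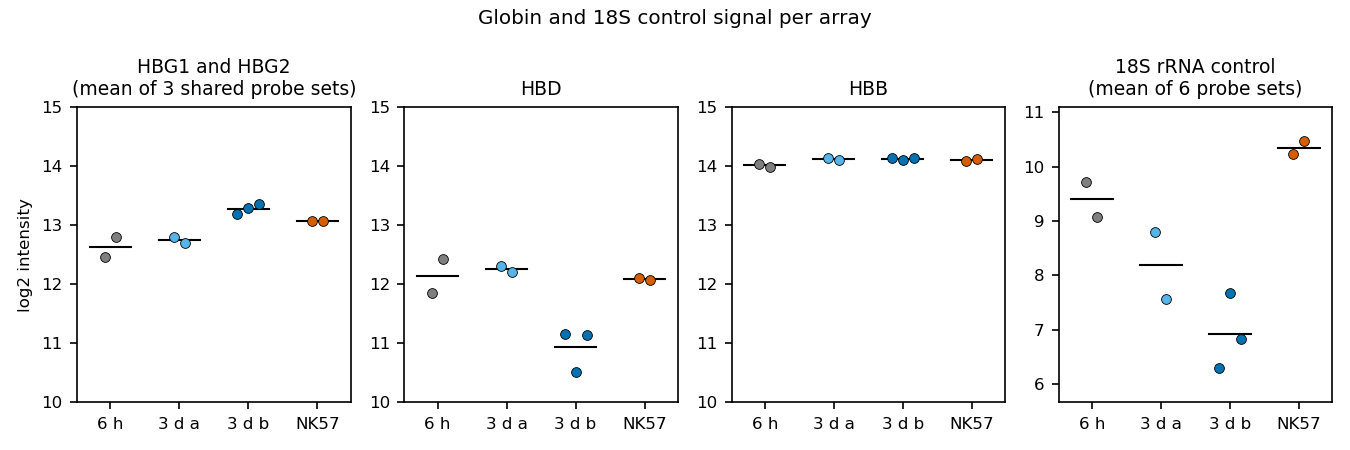
Log2 intensity per array (points) and mean (line) of fetal globin, HBD, HBB and the 18S ribosomal RNA control, for untreated cells at 6 hours, untreated 3-day cells of letters a and b, and NK57-treated cells. The globin panels share one axis range. Fetal globin under NK57 (13.07) lay between letter a (12.75) and letter b (13.28), and the 18S signal was highest under NK57 (10.35).

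Genes known to respond to inhibitors of histone deacetylases did not shift as a list, which like that of the deacetylases was chosen from recollection of the study. Of 17 tested, MT2A rose, H2BC21 and H2BC12 fell by 0.76 and 0.78 on the log2 scale, and 14 did not pass (median -0.16, camera adjusted p = 0.57). MT2A did not pass against letter a alone, at 0.33 (adjusted p = 0.125), and was at 0.52 against letter b. CDKN1A, a cell cycle inhibitor that such compounds commonly raise, had a change of -0.23 (95% interval -0.46 to 0.003, adjusted p = 0.119). Of 14 deacetylases and partners 2 rose and 2 fell (adjusted p = 0.752). SAP30 rose by 0.92, HDAC2 by 0.52 ± 0.14, HDAC6 fell by 0.65 on the log2 scale, and HDAC1 had a change of 0.20 (adjusted p = 0.329). With the mean of its probe sets SAP30 had a change of 0.24 that did not pass. HDAC2 did not pass under quantile normalization, at 0.30. Nor did it against letter a alone (adjusted p = 0.0667), where its change was 0.53, and it was 0.51 against letter b. Histone genes, with H2AC6 at -1.15, mitosis genes, with NUSAP1 at -0.72 and BUB1 at 0.51, and DNA replication genes, with GINS1 at 0.91 and UNG at 0.62, were not called as lists (adjusted p = 0.57, 0.35 and 0.35). BUB1 did not pass against letter a alone, under quantile normalization or with the mean of its probe sets, where its change was 0.07. CDKN1B was the 1 CDK inhibitor that fell. Its change was -0.82 against letter a alone, which did not pass (adjusted p = 0.0666), and -0.70 against letter b. Of 11 p53 targets BAX rose by 0.83 while 4 fell. The CDK inhibitor and p53 lists had camera adjusted p = 0.112 and 0.35. Of the p53 targets 1 passed as lower against letter a alone, 4 against letter b alone and 0 against both. BAX rose against both. Changes against letters a and b were -2.01 and -1.95 for GDF15, -1.38 and -0.75 for GADD45A and -0.43 and -0.46 for PHLDA3. They were -0.31 and -0.76 for TNFRSF10B and -0.16 and -0.93 for TP53I3. Interferon response genes went both ways, with ISG15 at 0.83 and ISG20 at -1.01.

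In the limma model 1458 genes were higher and 1125 lower under NK57, 27.6% of those tested, of which 256 and 60 changed by at least 2-fold. Groups did not overlap for 4902 genes, or 52.3%, where chance gives 9.52% if the arrays are independent. The NK57 arrays were the closest of all pairs and may be technical replicates, in which case chance would give more. Higher genes made up 56.4% of the calls, and 78.1% with arrays centred on their medians, 66.9% against letter a alone, 65.4% among genes above the median level, 52.2% under quantile normalization and 51.3% against letter b alone. With array weights the share was 45.0%, so that lower genes outnumbered higher ones, 2956 against 2419. In fits without the arrays of the other letter the counts were 1144 and 566 against letter a, 1950 and 1849 against letter b, and 963 and 400 in the same direction against both. In the model with the letters as groups they were 1425 and 1013 against letter a and 1729 and 1493 against letter b. They were 469 and 73 with the NK57 arrays averaged to 1 sample, 470 and 102 without NK57 replicate 1, 482 and 88 without NK57 replicate 2, and 24 and 0 with the 18S signal as a covariate. Without 3-day replicate 1b 706 genes were lower.

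The second comparison asked what changed in untreated cells between 6 hours and 3 days. Untreated 6-hour replicate 2 lay closer to 3-day replicates 1a, 3a and 3b than to the other 6-hour array. The SDs of the log2 difference were 0.193, 0.291 and 0.298, against 0.306. A wrong time label of 6-hour replicate 2 or 3-day replicate 1a could give this and would hide changes over time. A 6-hour replicate 1 unlike the other arrays could give it too, and neither was tested. That array was equally far from 6-hour replicate 2 and 3-day replicate 1a, with an SD of 0.306. Replicate 1a was also a control of NK57, and without it 1438 genes were higher and 1184 lower under NK57. No gene passed in the limma model, with 0 higher and 0 lower, and 666 genes had an unadjusted p under 0.05 where chance gives 468. The smallest adjusted p was 0.265, for the splicing kinase CLK1, whose change was 0.74 ± 0.12. Next among higher values were the glycine transporter SLC6A9 (0.97), USP48 (0.59), SNW1 (0.57) and CCNG1 (0.68), and among lower values UGGT1 (-0.66), MLLT3 (-0.67), G3BP1 (-0.72), RIDA (-0.68) and the proteasome gene PSMA4 (-0.59), all at adjusted p = 0.587. The shared HBG1 and HBG2 probe sets were at 12.63 ± 0.24 at 6 hours, and letter a and letter b lay 0.12 ± 0.14 and 0.65 ± 0.13 above that (adjusted p = 0.855 and 0.0168). Letter b was 0.53 above letter a, so its difference from 6 hours cannot be told apart from that between letters.

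Across this interval 3 lists were called, with 0 of their genes passing over all genes tested. Adjusted over the list alone, CEBPB of the amino acid stress list rose and HSP90AA1 and HSPH1 of the heat shock list fell. Cholesterol synthesis genes were higher at 3 days (median 0.35, 12 of 13 genes, camera adjusted p = 1.5e-05), as were amino acid stress genes (median 0.33, 13 of 14 genes, adjusted p = 2.3e-05), and heat shock genes were lower (median -0.36, 7 of 9 genes, adjusted p = 0.0047). With an estimated correlation the adjusted p was 0.634, 0.634 and 0.704. In the model with the letters as groups, cholesterol synthesis genes had a median of 0.16 in letter a and 0.50 in letter b against 6 hours, and heat shock genes -0.33 and -0.21, the latter not called (adjusted p = 0.329). The cholesterol call was lost in the fit with letter a controls alone, though not for letter a in the model with the letters as groups (camera adjusted p = 0.0442). The heat shock call was lost with letter b controls alone, with same-numbered arrays averaged and without 3-day replicate 1a. These shifts rested on 6-hour replicate 1, whose cholesterol score was -0.72 where replicate 2 had -0.004. Without replicate 1 there were 0 lists, without replicate 2 there were 10, and without 3-day replicate 3b there were 5. Against 6 hours, letter b alone gave 270 higher and 267 lower genes, or 175 and 165 in the model with the letters as groups, and leaving out 6-hour replicate 2 gave 37 and 9 and leaving out 3-day replicate 1a gave 3 and 12.

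The changes under NK57 and over time were set against each other across 9364 genes, which are not independent replicates. With the untreated 3-day arrays split so that none entered both changes, Pearson's r averaged -0.30 over 20 splits (SD 0.08, range -0.43 to -0.11). With all arrays in both, r was -0.45, where unchanged groups simulated against the same controls gave -0.28. The covariance was -0.040 against a simulated -0.0071. The simulated arrays were independent draws with no difference between letters. Most splits also put arrays of the same letter in both changes. What arrays of a letter share can lower r, and neither the simulation nor the splits remove it. Without 6-hour replicate 1 the split value was -0.09.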

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

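All tests in this part were chosen only after the result was seen, except the rescaling of fetal globin. Among the 5 untreated 3-day arrays, 1 array lay far from the other 4 for 7 of 84 genes or measures examined, and chance flags about 1 in 20. Array 3a was high for HPGD (6.39, next 5.56) and low for DDIT4 (9.78, next 10.29) and KLF1 (8.80, next 9.49). Array 3b was high for SAP30 (7.59, next 7.22) and CDKN1A (7.27, next 7.15). Array 1a was low for USP48 (8.12, next 8.46) and high for MLLT3 (7.65, next 7.20). Ribosomal RNA control probe sets, which no comparison uses, were higher on the NK57 arrays than on every untreated array, with a mean of 10.35 for 18S and 9.42 for 28S.

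Amino acid stress genes were lower under NK57, with a mean change of -1.01. If an array batch marked by the 18S signal were the reason, its trend among untreated arrays should give the greater part of that change. The trend predicted a change of -0.41 (95% interval -0.98 to 0.16). It was extended to an 18S signal of 10.35 under NK57, above the highest untreated array (9.72). With the 18S signal as a covariate the list stayed called (camera adjusted p = 7.8e-04). Its mean change then had an interval that includes 0 (-0.77, 95% interval -1.74 to 0.21, against -1.44 to -0.57 before). Over the 7 untreated arrays the list score and the 18S signal had r = -0.64 (exact permutation p = 0.078) and rho = -0.54 (exact permutation p = 0.236), the 1 relation computed, and r = -0.35 without the 2 arrays farthest out, but the trend rested on 6-hour replicate 1, without which r was -0.28, the predicted change -0.04 (95% interval -0.23 to 0.15) and the change with the covariate -0.94 (95% interval -1.22 to -0.66), so this 1 array keeps the explanation open. A state that untreated cells also enter may be part of it. The difference between the 6-hour arrays correlated with the NK57 change at r = 0.31 across all genes tested, not the list alone. That is only just past the 0.3 set for it. It rests on 1 pair of arrays whose likeness to NK57 had been noticed first, and the time label of replicate 2 may be wrong. Replicate 1 also had the higher 18S signal, 9.72 against 9.08, so this test cannot tell such a state from a batch marked by that signal. Lower transcription of the amino acid response stays open too, because amino acid transporters had a median of -0.98 while that of aminoacyl-tRNA synthetases, which that response also drives, depended on the scaling, with -0.17 as deposited (camera adjusted p = 0.313) and -0.38 under quantile normalization (adjusted p = 0.0116).

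CPA3 and FCER1A of the mast cell, basophil and eosinophil list and HPGDS, which is not in it, were higher under NK57, while 8 of the 11 genes of the list did not pass and the list was not called against the 5 untreated 3-day arrays. A larger share of mast cells would bring tryptase transcripts with it, and against letter b the larger tryptase change was 0.015 (limits -0.30 to 0.27) while the smallest change of CPA3, FCER1A and HPGDS was 2.09. Against letter a all 5 genes were higher, by 1.25 (CPA3) to 2.84 (HPGDS). Transcripts from other cells would reduce a gene's rise by an unknown amount, and tryptase was already high in letter b (TPSAB1 2.62 above letter a), so a larger share stays open against either letter. A change within such cells, or differences between cultures, stays open, and no other explanation was tested.

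Fetal globin under NK57 lay above letter a and below letter b. The signs held under quantile scaling and median centring, with a difference of at least 0.31 against letter a and of -0.11 or further from 0 against letter b. The intervals against letter b include 0, so a part of the normalization in it stays open. The control cells could differ in source, since HBD was lower in letter b, with a change of -1.33 (95% interval -1.75 to -0.90), while fetal globin was 0.53 higher. The labels name bone marrow and cord blood without tying either to an array, so source and letter cannot be told apart. The source of the NK57 arrays is not given either. Their HBD, 12.11 and 12.08, was nearer letter a (12.32 and 12.22), while their TPSAB1, 9.99 and 10.06, was like letter b. For fetal globin and the other genes called, a difference in source cannot be told apart from the treatment.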

How the results depend on the processing

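Averaging the NK57 arrays, calls against both letters, the 18S covariate, the 6-hour arrays as controls and the fit without array 3a and the 6-hour arrays were chosen after seeing the data. The cause of each change below was not tested unless stated. Genes higher under NK57, 1458 in the model as planned, numbered 256 at 2-fold or more, 2419 with array weights, 469 with the NK57 arrays averaged, 24 with the 18S covariate, 566 against the 6-hour arrays and 963 against both letters, and 470 to 1773 with each array left out. Genes lower, 1125 as planned, numbered 60, 2956, 73, 0, 155 and 400 under the same settings, 523 with arrays centred on their medians, 634 among genes above the median level, 566 against letter a, 1849 against letter b, and 88 to 1498 with each array left out. Averaging or leaving out an NK57 array leaves 1 sample, which is assumed to vary like the other groups. Adding the 18S covariate raised the median SE from 0.141 to 0.286 while the median size of called changes went from 0.577 to 0.496, and 2509 of 2583 called genes kept their sign.

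The 8 lists called under NK57 became 0 with an estimated correlation and stayed at 7 or 8 with each array left out. Heat shock, heme synthesis, ribosome biogenesis, red cell membrane and amino acid stress were called in the same direction in 25 of 25 other settings of the camera test. Erythroid transcription factors were called in 23 of 25, monocyte genes in 19 of 24 and lymphocyte genes in 15 of 24. Over time, higher genes numbered 270 with letter b alone, 1 with same-numbered arrays averaged and 0 to 37 with each array left out, and lower genes 267, 1 and 0 to 12. The 3 lists over time became 0 with an estimated correlation, 0 with fry, 6 among genes above the median level, 6 with the mean of a gene's probe sets, 5 with array weights and 0 to 10 with each array left out. The correlation of the changes was -0.45 with all controls in both and -0.37 to -0.089 with each array left out. Of 64 named genes called, 41 kept their call in every setting that tested them, 20 to 22 each, leaving aside the 18S covariate, a lone NK57 sample and the 6-hour controls. Signs turned for IFITM3 (0.69) and IL7R (0.028) with the 18S covariate and for MBD2 (-0.013) with the mean of its probe sets.

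Across groups, deviations of same-numbered arrays from their group means correlated at r between -0.17 and 0.16. This check could not settle whether the numbers pair arrays. The 3-day deviations were from a mean over both letters, and deviations of 2 arrays from their mean mirror each other. Same-numbered arrays within the 3-day group were not part of it. The model as planned treats the arrays as unpaired. With the number as a block 1228 genes were higher and 698 lower under NK57, and 0 and 0 over time. Dim probe sets near the background limit what a small change can show.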

Other observations

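The 10 gene families in this part were chosen after single genes had been seen, some of their members among them. Under NK57 genes of the mitochondrial ribosome rose in 37 of 50 cases (median 0.60, camera adjusted p = 1.8e-13), with MRPS28 at 1.37, MRPS12 at 1.30 and MRPL13 at 1.26. Respiratory complex I genes rose in 13 of 27 (median 0.43, adjusted p = 1.6e-07), and mitochondrial import and outer membrane genes in 10 of 19 (median 0.42, adjusted p = 4.5e-05), led by VDAC1 at 2.05. The cytosolic chaperonin rose in 6 of 7 (median 0.68, adjusted p = 3.6e-05), the proteasome in 13 of 33 with 1 fall (median 0.36, adjusted p = 1.1e-06) and glycolysis in 10 of 16 with 2 falls (median 0.66, adjusted p = 4.5e-05), with LDHA at 1.33 and PGK1 at 1.31. With an estimated correlation these 6 families had adjusted p = 0.0393.

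Amino acid transporters fell in 7 of 9 cases with 1 rise (median -0.98, adjusted p = 1.6e-04, and adjusted p = 0.187 with an estimated correlation), with SLC7A5 at -1.30 and SLC3A2 at -0.98. Serine, glycine and one-carbon enzymes, with CBS at -1.39, were not called (adjusted p = 0.0590), nor were aminoacyl-tRNA synthetases (5 fell, 2 rose of 16, median -0.17, adjusted p = 0.313) or cytosolic ribosomal proteins (2 rose of 55, median 0.04, adjusted p = 0.142). Under quantile normalization the serine and synthetase families were called as lower (adjusted p = 0.0117 and 0.0116), and with arrays centred on their medians the serine family was called as lower and the cytosolic ribosome as higher (adjusted p = 0.0233 and 0.0401). With an estimated correlation and the deposited scaling these 3 families had adjusted p = 0.221, 0.464 and 0.469. All 10 families kept the sign of their median against letter a alone, against letter b alone and under both scalings, but sizes moved. Under quantile normalization the medians were 0.39 for the mitochondrial ribosome, 0.22 for complex I, 0.15 for the proteasome, -0.38 for the synthetases and 0.003 for the cytosolic ribosome, and the median of the cytosolic ribosome was 0.13 with centred arrays. Between the untreated 6-hour arrays, replicate 1 minus replicate 2 had the same sign as the NK57 change for 69.4% of the genes higher and 69.2% of those lower under NK57, against 58.8% of all genes tested. The medians of this difference had the sign of the NK57 median in all 10 families. They ran from -0.70 for amino acid transporters and -0.52 for the serine family to 0.31 for the cytosolic chaperonin.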
